A study of Mus musculus with 2 samples.

How the data were processed

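Gene expression was measured in hair follicles of mice at postnatal day 10, on 2 Affymetrix mouse expression arrays of 1 design. One array held RNA from wild-type mice and the other RNA from mice carrying a transgene for dnFGFR2-IIIb, a form of the IIIb splice variant of fibroblast growth factor receptor 2. Per the labels, each array received total RNA, isolated with Trizol, from a pool of about 300 follicles, to which each of 3 mice from separate litters gave about 100. Probe preparation and hybridisation followed the manufacturer's protocol, per the labels.

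The deposited values are one linear intensity per probe set, which the authors had scaled so that the 2% trimmed mean over all probe sets was 100 on each array, as the values themselves show. The summary algorithm and its version are not given in the sources used here. The values were used as linear intensities with arbitrary units, and the medians were 15.4 on the wild-type array and 17 on the transgenic array. A global scaling of this kind sets the arrays to the same total signal, so a shift shared by all genes cannot be seen, and every ratio is relative to the bulk of the transcripts.

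The 64 control probe sets were left out of the comparison, and 45037 of the 45101 probe sets remained. In the platform annotation, 34945 of these had 1 gene symbol, 932 had several and 9160 were not named. Names were checked through gene identifiers against a RefSeq gene table of assembly GRCm38.p6. With the controls that carry a symbol, 34754 probe sets matched it, 0 of them under another symbol, and 204 kept the platform's name. No gene was named from a probe set with several symbols. No coordinates are given because the values carry none, and the table served only for names and for the order of neighbouring genes.

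Both columns were rescaled to the same 2% trimmed mean over non-control probe sets, which changed the deposited values by negligible factors. Values under a floor were set to the floor, which was the 40th percentile of both arrays and came to 10.5. Each gene was represented by its probe set with the highest mean over the arrays. A gene counted as higher or lower on the transgenic array when both signals exceeded the floor and differed at least 2-fold. Where 1 signal lay under the floor, the ratio to the floor is a lower bound and is written with "at least". The named genes were the 15 with the largest and the 15 with the smallest ratio, up to 4 members with the largest absolute log2 ratio from each fixed list, and every probe set of Fgfr2, Igfbp5 and Foxn1. A further probe set of a named gene is given where it went the other way or was under 50% of the size on the log2 scale. Genes named outside this rule are said to have been chosen after their values were seen.

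For 34 lists of pathway genes and cell type markers, the median log2 ratio was taken over members above the floor on at least 1 array. It is described by its percentile among 10000 random lists of the same size, matched on expression in 20 bins. The arrays, 1 per group, give no replicate spread and no p-values, and the percentiles describe these 2 arrays, not the conditions. The spread behind a gene's ratio was taken as the SD of log2 ratios between probe sets of the same gene, by tertile of brightness. This spread is technical and specific to probes, and leaves out the differences between mice, which pooling hides. The small number of arrays limits the precision of every value.

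The procedure was tested on simulated data made from the signals of all 18193 genes in the transgenic against wild-type comparison, with normally distributed noise of the size seen between probe sets. Of 50 genes changed by each known fold, the 2-fold rule called 12% at 1.5-fold, 52% at 2-fold, 88% at 3-fold and 78% at 4-fold. A call needed both signals above the floor, so that a dim gene with a large change can drop out. Each percentage rests on a single draw of genes. Of 200 random lists of 20 genes, 6% fell outside the central 95%, and 100% of 50 lists shifted by 0.5 on the log2 scale were found. The random lists came from the same independent simulated genes as their reference lists, so a share close to the nominal one was built in. The shift of 0.5 is larger than most list medians reported below, so it does not show how often smaller shifts would be found.

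The groups, the rules, the lists and most alternative settings were fixed before the data were examined. These settings were equal medians, no rescaling, quantile normalization, an intensity-dependent loess with a span of 0.3, floors at the 20th and 60th percentiles, and a pseudocount of the floor's size in place of the floor. Further ones were the mean over a gene's probe sets, leaving out probe sets that can match several transcripts, thresholds of 1.5-fold and 3-fold, counting probe sets instead of genes, and random lists without matching. A floor of 50 and a scaling to equal spiked hybridisation controls were added after seeing the data, because the planned floor lay within the range of controls that have no target in the mouse. For markers of B cells and of neutrophils, for X-linked genes that escape inactivation, for retinoid genes and for a gene cluster, lists were likewise added later, and their results stand in the closing observations. Under the alternatives 2000 random lists were drawn. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.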

Results

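Targets of signalling through the IIIb form of fibroblast growth factor receptor 2 (FGFR2) in the hair follicle were sought by comparing follicles of wild-type mice with follicles of dnFGFR2-IIIb transgenic mice. The data comprised 1 array per group, each from a pool of about 300 follicles from 3 mice at postnatal day 10. There were no replicate arrays, and pooling hides the spread between mice, so that differences are described for these 2 arrays and not tested. Of the non-control probe sets, 26426 (58.7%) on the wild-type array and 27613 (61.3%) on the transgenic array gave a signal above the floor of 10.5. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.89 and 2.06 for beta-actin and 0.796 and 0.852 for Gapdh on the wild-type and transgenic arrays. Of the 27 control probe sets without a target in the mouse, 0 exceeded the floor on the wild-type array and 3 did on the transgenic array, where the brightest read 15.8. Signals under about this level are thus near the background, and ratios that rest on one, bounds against the floor included, are uncertain.

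The probe sets of Fgfr2 that exceeded the floor differed by under 2-fold, with ratios above 1. Its brighter probe set, 1433489_s_at, read 197 on the wild-type array and 368 on the transgenic array, a 1.87-fold difference, and 1420847_a_at read 147 and 206, a 1.41-fold difference. The remaining Fgfr2 probe set lay under the floor on both arrays. Whether any of these probe sets lies within the transgene is not known here, so that they do not check the labels.

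The gene with the largest difference between the arrays was Ighm, annotated as the immunoglobulin mu heavy chain gene. Its brightest probe set read 20.7 on the wild-type array and 10146 on the transgenic array, a 490-fold difference. Its other probe sets above the floor on both arrays gave log2 ratios of 9.42, 0.47 and -0.34, so which heavy chain RNA was read is not settled. The next largest ratios were those of Irx1, a homeobox transcription factor (14.5 and 74.2, 5.12-fold), and Igfbp5, a secreted binding protein of insulin-like growth factors (135 and 688, 5.11-fold). The other probe set of Igfbp5, which was dim, read 17.9 and 22.9, a log2 ratio of 0.36. The genes with the lowest ratios included Krt84, a hard keratin, which read 619 and 29.4 and was thus 21.1-fold lower on the transgenic array, and the cornified envelope genes Lce3c (12.4-fold lower), Sprr1b (5.75-fold lower) and Sprr2h (4.85-fold lower). Foxn1, a transcription factor of the differentiating hair shaft, read 759 and 775 with one probe set and 354 and 399 with the other.

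Across the 11565 genes above the floor on both arrays, 185 were at least 2-fold higher and 183 at least 2-fold lower on the transgenic array, together 3.18%. A further 214 genes above the floor on the transgenic array alone and 153 above it on the wild-type array alone lay at least 2-fold from the floor. The log2 signals had a Pearson correlation of 0.978 across genes, which are not independent replicates. Most of the 2-fold differences were in dim genes. The SD of log2 ratios between probe sets of the same gene was 0.50 in the dim tertile, 0.34 in the middle and 0.28 in the bright tertile, and the tertiles held 159, 17 and 9 of the higher genes and 138, 28 and 17 of the lower genes. With noise of this size and no difference between the arrays, 100 simulations gave a median of 89 higher and 88 lower genes. Among genes with a signal over 100 on the brighter array, 24 were higher and 49 lower, against a simulated median of 8 each and maxima of 13 and 15. In these simulations the noise was normal with a single SD per tertile, and noise with a heavier tail would pass 2-fold more often. The comparison therefore does not decide how many genes differ beyond noise. The split between higher and lower genes depended on the scaling. With equal medians, which moved the median log2 ratio of all genes to -0.14, it was 115 higher and 296 lower, and with equal spiked controls, which moved it to 0.19, it was 315 and 103. List medians move by about as much under these scalings, so that the sign of a smaller one depends on the scaling. Quantile normalization gave 139 and 230, loess 131 and 239, and a floor of 50, chosen after seeing the data, 22 and 37.

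**Figure D1:**
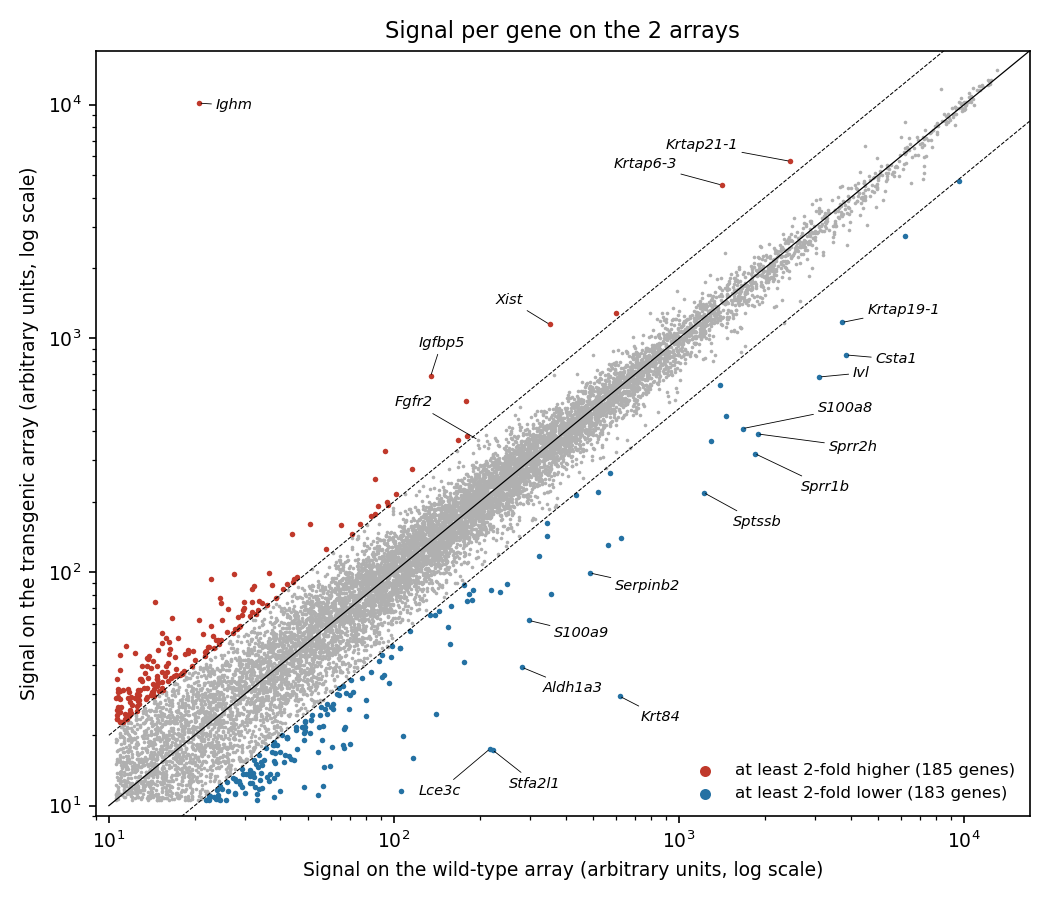
Signal of each gene on the wild-type array (horizontal) and the transgenic array (vertical), both in arbitrary units on log scales, for the 11565 genes above the floor on both. Each point is 1 gene, the solid line marks equal signals and the dashed lines a 2-fold difference; Ighm stands apart at 20.7 and 10146, and most coloured points lie at low signals.

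Further genes with low ratios included Stfa2l1, of the stefin family of cysteine protease inhibitors (222 and 17.3, 12.8-fold lower), and Serpinb2, a serine protease inhibitor of the plasminogen activator system, which read 487 and 99.0 (4.92-fold lower). S100a9, which encodes a calcium-binding protein, read 298 and 62.0 (4.81-fold lower). Involucrin (Ivl, 3110 and 683), named through its list, went the same way, as did the stefin Csta1 (3861 and 848) and S100a8 (1671 and 411), whose protein pairs with that of S100a9, which were both chosen after their values were seen. A second probe set of Ivl gave a log2 ratio of -2.07 beside the -2.19 of the brighter one. Lce3c, Sprr1b, Sprr2h and Ivl belong to gene families with similar sequences, or sit among them, so that signal shared between family members makes these values uncertain.

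The other genes with the lowest ratios had diverse known functions. Aldh1a3, which encodes a retinaldehyde dehydrogenase that makes retinoic acid, read 281 and 39.1 (7.19-fold lower), with a log2 ratio of -1.78 at its other probe set. Sptssb, a small subunit of serine palmitoyltransferase in sphingolipid synthesis, read 1221 and 219 (5.59-fold lower), and the transcription factor Snai3 read 140 and 24.6 (5.69-fold lower). Ddhd1, a phospholipase gene, read 117 on the wild-type array (7.29-fold lower on the transgenic array), and Calcb, which encodes a calcitonin gene-related peptide, read 107 and 19.9 (5.39-fold lower). Zbtb16, a zinc finger transcription factor, read 106 and 11.6, but its other probe set read 18.3 and 18.7. Clec2d (54.1 and 11.1) and Scrg1 (56.5 and 12.1) completed the list and were dim on both arrays. Of the 45 lower genes that had a further probe set above the floor on both arrays, 22 went the same way in all such probe sets and 12 were also 2-fold lower in at least 1 of them.

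The higher genes after Igfbp5 were mostly near the floor on the wild-type array. They were Gm20199, Inpp5j (22.9 and 93.0), Alkbh2, the epidermal keratin Krt77 (16.6 and 63.8), Oip5, the platelet chemokine gene Pf4 (15.3 and 54.8), Gm9789, Exosc1, Zic1, Atoh7, Apoc4 and Tsks, with log2 ratios from 2.07 for Gm20199 to 1.71 for Tsks. Exosc1, which encodes a subunit of the RNA exosome, read 93.0 and 329 at its brightest probe set, while the others gave log2 ratios of 0.66 and -0.49. Atoh7 read 43.9 and 145, with a log2 ratio of 0.28 at its other probe set. Of the 48 higher genes with a further probe set, 32 went the same way in all and 9 were also 2-fold higher in at least 1.

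Immunoglobulin signal was restricted to a few probe sets. Of 23 heavy chain probe sets on the arrays, 3 exceeded 1000 on the transgenic array, all annotated to Ighm, with 10146, 9002 and 8361 against 20.7, 9.0 and 12.2 on the wild-type array. The other heavy chain probe sets read at most 26.9 on either array, among them further Ighm probe sets, with log2 ratios of 0.47 and -0.34 where both signals exceeded the floor. The annotation therefore does not settle which heavy chain RNA the 3 bright probe sets read. The 33 light chain probe sets read at most 17.9 on the transgenic array and 13.8 on the wild-type array.

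Sex-linked genes differed between the pools. Of the Y-linked genes, Eif2s3y read 191 on the wild-type array and lay under the floor on the transgenic array, at least 18.2-fold lower, Kdm5d was at least 5.27-fold lower and Uty at least 2.98-fold lower. One dim probe set of Kdm5d went the other way, from 6.10 to 17.1. Xist, the RNA transcribed from the inactive X chromosome, read 352 and 1146, 3.25-fold higher, and was 2.67-fold and 4.61-fold higher at its other probe sets. The median log2 ratio of these 4 genes was -1.99, below that of every one of 10000 matched random lists. This difference ran alongside every comparison of genotype reported here.

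Pathway lists of growth factor signalling showed few large differences. Of 14 measured FGF ligands and receptors, 0 were 2-fold higher and 1, Fgfr1, was 2-fold lower (67.9 and 30.3, log2 ratio -1.16), with log2 ratios of 0.91 and -0.14 at its other probe sets, and the median was -0.03 (percentile 30.0). Fgfr4 was at least 2-fold lower but near the floor, at a log2 ratio of -1.12, and Fgf18 lay under the floor on the transgenic array. Of 17 genes known as targets or feedback inhibitors of FGF and mitogen-activated protein kinase signalling, 11 had a ratio under 1 and Dusp5, a phosphatase of that pathway, was 2-fold lower, at 249 and 88.7. Etv4, with a log2 ratio of -0.70 but 0.43 at its other probe set, Dusp4 (-0.66) and Ets1 (0.68, and from -0.51 to 0.23 at its other probe sets) followed in size, and the list's median of -0.14 lay at percentile 4.71 and became 0.05 with equal spiked controls. Of 16 genes of the insulin-like growth factor axis, 11 had a ratio above 1 and the median was 0.23 (percentile 97.3). Igfbp5 was the member that passed 2-fold on both arrays, Irs2, an adaptor of the insulin receptor, was at least 2.98-fold higher, and Igf2bp3, an RNA-binding protein, had a log2 ratio of 0.65 and lower ones, down to 0.03, at its other probe sets. The 11 measured genes of the epidermal growth factor family had a median of -0.08 (percentile 21.9), with Hbegf at -0.61, but 0.30 at its other probe set, and Errfi1 at -0.51.

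Most genes of the hair shaft and inner root sheath read alike on both arrays, with exceptions of large size. These lists are bright, with median signals of 7862 for hair shaft keratins, 5786 for keratin-associated proteins and 4225 for the inner root sheath. The array maxima were 13964 and 14817. Whether ratios are compressed at such signals was not tested, so that a ratio near 1 may understate a difference. Among 12 hair shaft keratins, Krt84 was 21.1-fold lower, and the log2 ratios of the others lay between -0.22 for Krt32 and 0.27 for Krt35. The list had a median of 0.06 (percentile 96.6) and a mean of -0.32, which differ in sign because of Krt84. Of 36 keratin-associated proteins, which cross-link the keratins of the hair shaft, 3 were 2-fold higher and 3 lower, with a median of -0.03 (percentile 58.4). Krtap6-3 read 1412 and 4526 (3.21-fold higher, with a log2 ratio of 1.41 at its other probe set) and Krtap21-1 read 2454 and 5720 (2.33-fold higher). Krtap19-1 read 3738 and 1170 (log2 ratio -1.68), but went the other way at a dimmer probe set (0.37), and Krtap19-4 read 6190 and 2753 (-1.17). These genes lie in families of similar sequence, so that signal shared between probe sets makes these values uncertain.

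In the inner root sheath and companion layer, 3 of 21 genes were 2-fold lower and 0 higher, with a median of -0.05 (percentile 30.7) over a set in which most ratios were close to 1. The lower ones were Dsc2, a desmosomal cadherin (624 and 140, log2 ratio -2.15, with -2.04 at its other probe set), Tchhl1, a relative of trichohyalin (1296 and 365, -1.83), and the transglutaminase Tgm3 (1393 and 628, -1.15). Padi1, which converts arginine in proteins to citrulline, followed at -0.84. Among 15 genes of the medulla and its regulators, Igfbp5 was 2-fold higher and Barx2, a homeobox gene, was under the floor on the transgenic array and at least 2-fold lower (log2 ratio -1.95), with Fgf5 at 0.75 (0.11 at its other probe set) and a median of -0.02 (percentile 47.9). Of 25 transcription factors of the hair follicle, Runx3 was 2-fold lower (35.9 and 13.2), Foxq1 had a log2 ratio of -0.67 and -0.27 at its other probe set, and Dlx4 0.55 and 0.13. Their median was 0.02 (percentile 63.2), and 0.14 (percentile 98.7) with the mean over probe sets. The 14 desmosome genes had a median of -0.03 (percentile 45.3), with Dsg2 (-0.66) after Dsc2, and Dsg2 went the other way at a dim probe set (0.79).

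Genes of the outer root sheath, basal layer and bulge read lower on the transgenic array by a small amount. Of 24 genes, 20 had a ratio under 1 and 0 were 2-fold apart, with a median log2 ratio of -0.21, at percentile 0.14 of matched random lists, and a median of -0.01 with equal spiked controls. The largest differences were in Cd34, a bulge marker (77.6 and 41.4, log2 ratio -0.91), Nfatc1 (-0.80, but 1.25 and 0.21 at dim probe sets), Itgb4, an integrin of hemidesmosomes (101 and 60.8, -0.74), and Krt6b, which lay under the floor on the transgenic array. Markers of melanocytes also read lower, with a median of -0.21 at percentile 0.18, which became -0.02 with equal spiked controls, 13 of 18 ratios under 1 and 0 of them 2-fold apart. Mc1r, the melanocortin receptor, read 204 and 108 (log2 ratio -0.92), Mlana -0.66, Gpnmb -0.63, with 0.21 at a dim probe set, and Rab38 -0.62. Markers of Schwann cells and nerve had a median of -0.42 (percentile 1.11, 10 genes), with S100b (45.3 and 21.7, -1.06), Ngfr (-0.97), Fabp7 (-0.81) and Sox10 (-0.57). With a floor of 50, chosen after seeing the data, 5 Schwann and nerve genes remained, at -0.19 and percentile 6.5.

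Markers of the interfollicular epidermis, which can adhere to isolated follicles, read higher as a list but went both ways. Of 22 genes, 14 had a ratio above 1, and the median was 0.24 (percentile 99.95), from 0.096 with equal medians to 0.43 with equal spiked controls, while 2 were 2-fold higher and 2 lower with both signals above the floor. Lce3a was at least 7.49-fold lower and Ivl was 4.55-fold lower, whereas Krt77 was 3.84-fold higher and Krt78 at least 3.08-fold higher. Krt10, a keratin of the suprabasal epidermis (150 and 225), and loricrin (Lor, 78.6 and 130), chosen after their values were seen, had ratios above 1 but under 2-fold. Markers of immune cells had a median of 0.51 (percentile 99.7, 17 genes, 14 with a ratio above 1), but most lay near the floor. H2-Aa was at least 4.04-fold higher at 42.4, Cd74 read 11.2 and 22.9, and C1qa and H2-Eb1 lay under the floor on the wild-type array. With the floor at the 60th percentile, 5 immune genes remained, with a median of 0.03.

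**Figure D2:**
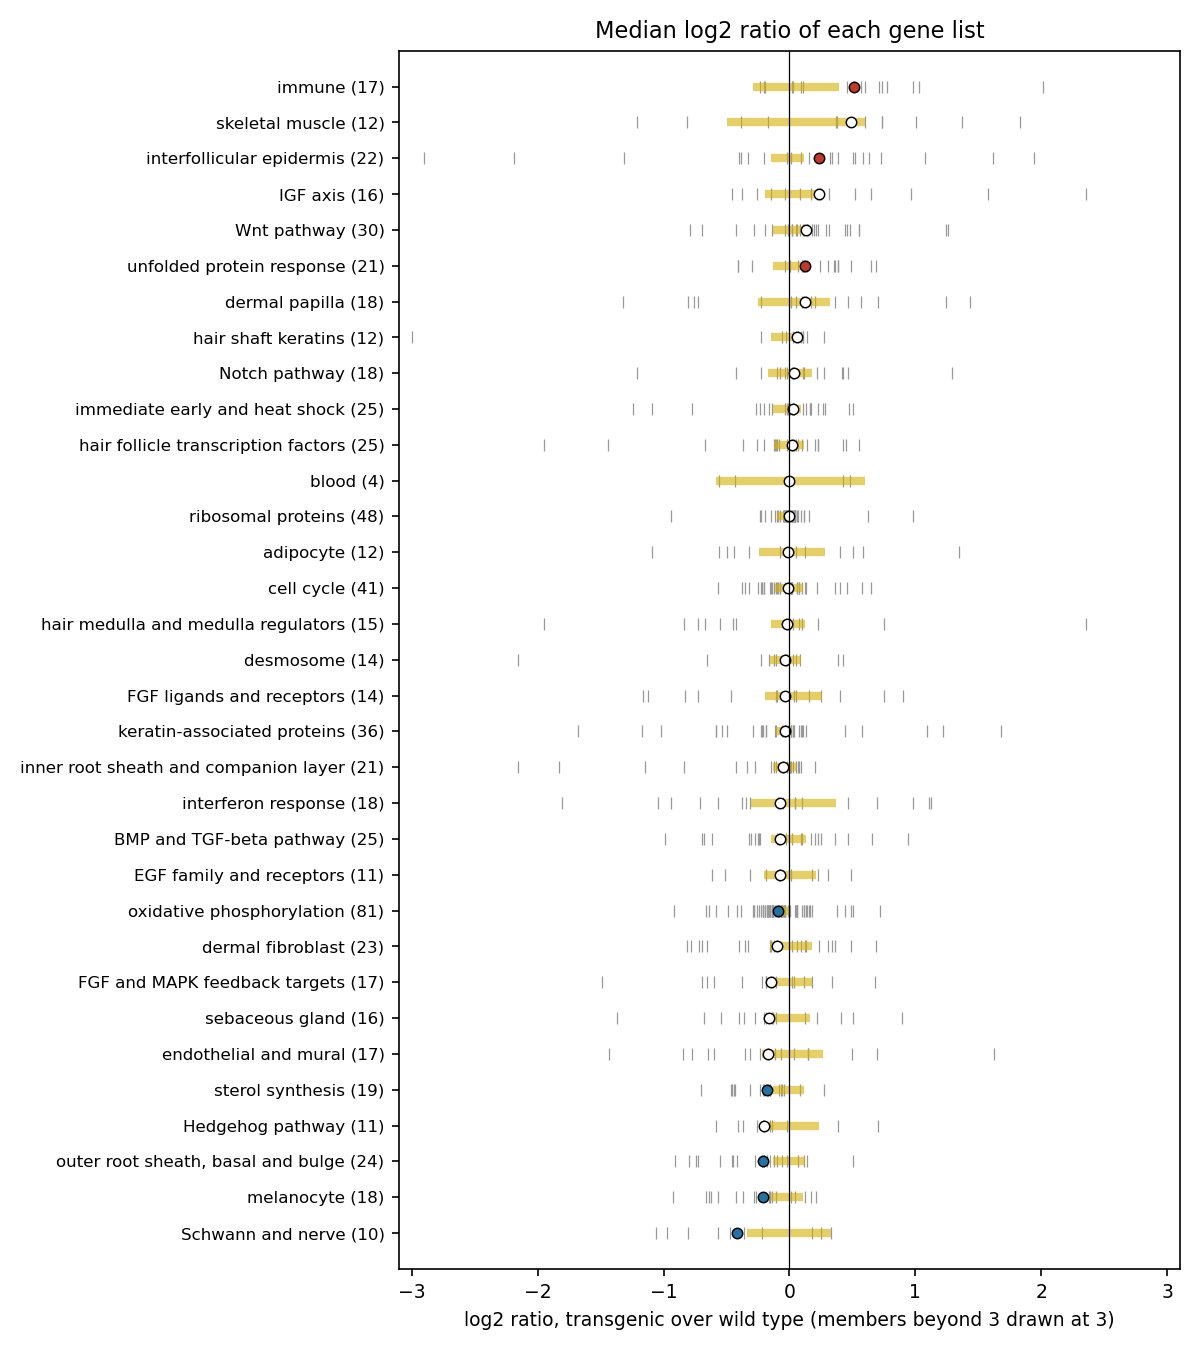
Median log2 ratio of transgenic over wild-type signal (circles) for 33 gene lists, with the number of measured members in brackets, each member as a grey tick and the central 95% of 10000 matched random lists as a yellow bar. Filled circles lie outside that range, blue for lower and red for higher; the sex-linked list, at -1.99, is not drawn, and among the filled circles the signs for the unfolded protein response, sterol synthesis and oxidative phosphorylation depend on the scaling.

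Shifts of small size were seen in lists of metabolism. Of 19 genes of sterol synthesis, 17 had a ratio under 1 and the median was -0.18 (percentile 0.375), which became 0.02 with equal spiked controls. Dhcr7, which catalyses the last step to cholesterol, read 323 and 199 (log2 ratio -0.70), Lss -0.46, Tm7sf2 -0.45, and Msmo1 -0.44 with 0.18 at a dim probe set. Of 81 genes of oxidative phosphorylation, 61 had a ratio under 1, with a median of -0.09 (percentile 0.72) that became 0.10 with equal spiked controls, and Ndufaf5 (-0.91) and Ndufaf4 (0.72) lay farthest out. The list fell within the central 95% with quantile normalization (-0.046, percentile 3.025) and with loess (-0.052, percentile 2.9). The unfolded protein response had 17 of 21 ratios above 1 and a median of 0.13 (percentile 99.3), which became -0.01 with equal medians. It fell within the central 95% with unmatched random lists (percentile 88.85) and without probe sets that can match several transcripts (percentile 97.05). Its largest log2 ratios were 0.68 for the stress transcription factor gene Ddit3, 0.64 for Pdia4 and 0.49 for Sdf2l1. In each of these 3 lists 0 genes were 2-fold apart. The 48 ribosomal protein genes had a median of -0.01 (percentile 86.9) and 0 of them were 2-fold apart, with Rps27 at 0.98 and Rps6 at -0.94.

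The remaining signalling lists lay within the central 95% of random lists. The 41 cell cycle genes had 0 members 2-fold apart and a median of -0.01 (percentile 40.5), with Cenpe at 0.64 and Ttk at 0.58. Of 30 Wnt pathway genes, Wnt3 (12.5 and 30.0) and Rspo3 (14.7 and 34.9) were 2-fold higher but near the floor, Wnt10b had a log2 ratio of -0.79 and Sfrp1 one of -0.70, with values from -1.03 to 0.60 at its other probe sets, and the median was 0.13 (percentile 96.5). The 11 Hedgehog genes had a median of -0.20 (percentile 3.70), with Hhip at 0.70, Gli3 at -0.58 and Shh at 0.38 (0.11 at its other probe set). The 25 genes of BMP and TGF-beta signalling had a median of -0.07 (percentile 15.7), with Tgfbi at -0.99 (-0.18 at another probe set) and Gdf10 at 0.94, and the 18 Notch genes one of 0.03 (percentile 61.7), with Hes5 (10.8 and 26.5) higher and Dll4 (24.5 and 10.6) lower. For the interferon response, 18 genes gave a median of -0.07 (percentile 24.1) with Bst2 lower at 38.1 and 10.9, and for immediate early and heat shock genes 25 gave 0.03 (percentile 79.4) with Fosl1, a partner of Jun in AP-1, 2.36-fold lower at 39.9 and 16.9.

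Of the other cell types, dermal papilla markers had a median of 0.12 (percentile 74.1, 18 genes), with Ndnf (11.7 and 31.7) and Rspo3 higher and Sox18 under the floor on the transgenic array. Dermal fibroblast markers had a median of -0.10 (percentile 9.72, 23 genes), with Pdgfrb at -0.81 (-0.19 at its other probe set) and Eln at -0.78. Sebaceous gland markers had a median of -0.16 (percentile 4.04, 16 genes), with Plin2, a lipid droplet protein, at 974 and 610. Endothelial and mural markers had a median of -0.17 (percentile 5.99, 17 genes), with Cdh5 (13.7 and 42.3) higher and Egfl7 lower (-1.43, but from -0.34 to 0.29 at its other probe sets). The endothelial median was -0.27 (percentile 2.2) with the 20th percentile floor, -0.31 (percentile 2.25) with the 60th and -0.29 (percentile 0.35) with a floor of 50. Adipocyte markers had a median of -0.01 and a mean of 0.00 (percentile 43.2, 12 genes), with Adipoq, the adiponectin gene, 2.13-fold lower (139 and 65.3). With the 60th percentile floor 8 adipocyte genes remained, with a median of -0.38 below that of every one of 2000 random lists, and a floor of 50 gave -0.32. Skeletal muscle markers, mostly near the floor, had a median of 0.49 (percentile 91.8, 12 genes), with Acta1 at least 3.55-fold higher and Eno3 lower but near the background on the transgenic array. The 4 blood markers had a median of 0.00 (percentile 46.6), with Hbb-b2 at -0.56 and Alas2 at 0.49. In all, 9 of 34 lists, the sex-linked one among them, lay outside the central 95%, 3 above and 6 below. Independent lists of independent genes would give 1.7. Since lists share members and genes of a list can vary together, that number is no yardstick for a test.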

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

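The tests of B cells, of transgene RNA, of epidermis and of sex make-up for the cornified envelope pattern were chosen only after the result was seen, whereas those of neutrophils and of genes escaping X inactivation were fixed before their result was seen.

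The 3 Ighm probe sets with signals from 8361 to 10146 on the transgenic array were in the range of hair keratins, yet B cells or plasma cells would bring light chains at similar levels. The brightest light chain probe set on that array read 17.9 and the B cell markers Cd79a, Cd79b and Ms4a1 lay under the floor, with the plasma cell gene Mzb1 at 26.9, which argues against such cells. Blnk, an adaptor gene on the same list, was above the floor on both arrays but lower on the transgenic array (527 and 308). A candidate explanation is transgene RNA that carries a part of the immunoglobulin heavy chain, since fusions to that part are a known way to build soluble receptors. The labels do not give the construct, and the Fgfr2 probe sets, 1.87-fold apart at most, do not decide because their place in the construct is unknown. No other explanation of this signal was tested.

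The lower signals of the cornified envelope genes Lce3c, Sprr1b, Sprr2h and Ivl, the stefins Stfa2l1 and Csta1, S100a8 and S100a9 on the transgenic array were grouped after the values were seen, without a test of enrichment, and other cornified envelope genes such as Sprr1a (9373 and 9614) and Lor (78.6 and 130) were not lower. Sprr1a was bright, and whether ratios are compressed at its level was not tested. The lower signals of the group could reflect tissue carried along with the follicles. Less interfollicular epidermis in the transgenic pool would lower the epidermal markers as a list, but their median log2 ratio was 0.24, with a range from 0.096 to 0.43 under the alternatives. The list as a whole was thus not lower. It went both ways, with 14 ratios above 1 and 8 under 1, and holds Ivl itself, so that its median does not decide for the lower genes. More neutrophils in the wild-type pool, a source of S100a8 and S100a9, would bring other neutrophil transcripts, but the brightest of 8 granule protein and receptor markers on the wild-type array, Ltf, read 8.30 against 1671 for S100a8. Of the other genes on that list, Lcn2 read 19.6 and Lyz2 21.6 on the wild-type array, and the list's median log2 ratio was 0.37 (percentile 89.6). A different sex make-up stays open, with Y-linked genes at no more than 8.60 at their brightest probe sets on the transgenic array, and 17.1 at a dim one of Kdm5d, because it goes together with genotype in these pools. The transgene itself, the difference the design names, and differences between the litters stay open too and were not tested.

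Higher Xist and lower Y-linked signals on the transgenic array are consistent with pools of different sex make-up, with males contributing to the wild-type pool and few or none to the transgenic pool. X-linked genes that escape inactivation, which are expressed from both X chromosomes in females, had a median log2 ratio of 0.57 (percentile 99.99, 8 genes), among them Kdm6a at 0.82, Eif2s3x at 0.68 and Kdm5c at 0.62. One of them, Ddx3x, went the other way at -0.12. No other explanation was tested for this pattern, and any difference between the pools may carry a part due to sex.

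Outside the named genes, the control probe set for the 5' part of 18S ribosomal RNA read 3655 on the wild-type array and 10275 on the transgenic array, a 2.81-fold difference, while that for the 3' part read 538 and 660 and that for the middle part 174.7 and 167.5. Among probe sets without a gene name, 126 were at least 2-fold higher on the transgenic array and 45 at least 2-fold lower, of 2614 above the floor on both. Most of the 126 were dim on both arrays. Over all probe sets, named or not, 576 were higher and 381 lower, and the split between higher and lower genes depended on the scaling. The brightest of the higher unnamed probe sets, 1424609_a_at, read 598 and 1601, a 2.68-fold difference, and 1424607_a_at read 522 and 1310, a 2.51-fold difference. Among the lower unnamed probe sets, 1416325_at read 953 and 164 (5.80-fold lower), 1417695_a_at 1410 and 679 (2.08-fold lower) and 1449077_at 494 and 176 (2.80-fold lower).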

How the results depend on the processing

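The floor of 50 and the scaling to equal spiked controls were chosen only after the data were seen, and the other alternatives were planned. No paired analysis was possible because there was 1 array per group, and for the same reason leaving out 1 array was not possible and no other split of the samples exists. The percentiles do not measure the spread between mice.

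Against 185 genes higher and 183 lower (368 in all), a floor at the 20th percentile gave 845 and 685 (1530), one at the 60th percentile 50 and 61 (111), a pseudocount 53 and 76 (129), and a floor of 50 gave 22 and 37 (59), with 37.3% higher. The floors admit different numbers of dim genes, and the pseudocount shrinks their ratios. A threshold of 1.5-fold gave 735 and 784 (1519), 3-fold 27 and 40 (67), and probe sets instead of genes 576 and 381 (957). With equal medians 115 were higher and 296 lower (28.0% higher), of which 104 and 169 were also called in the main setting. Quantile normalization gave 37.7% and loess 35.4% higher. Equal spiked controls gave 315 and 103 (75.4% higher), with 165 and 97 shared. Among genes over 100 on the brighter array, more were lower than higher under each scaling but equal spiked controls, where 58 were higher and 32 lower.

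Shifting all ratios, equal medians moved the list medians to -0.35 for the outer root sheath, -0.32 for sterol synthesis, -0.24 for oxidative phosphorylation, -0.35 for melanocytes and 0.10 for the epidermis, and turned the unfolded protein response to -0.015. Equal spiked controls moved them to -0.012 for the outer root sheath, 0.32 for the unfolded protein response, -0.018 for melanocytes, 0.43 for the epidermis and -0.22 for Schwann cells and nerve, and turned sterol synthesis to 0.015 and oxidative phosphorylation to 0.10. Quantile normalization gave -0.046 and loess -0.052 for oxidative phosphorylation, within the central 95%. The epidermis had 0.16 with the 20th percentile floor and without probe sets that can match several transcripts, 0.13 with the 60th and 0.12 with a floor of 50. Immune markers had 0.77 and 0.029 with the lower and higher planned floors. The sex-linked list had -2.70 and -0.59 with these floors, -1.62 with the pseudocount, -1.06 with the mean over probe sets and -0.15 with a floor of 50. With the floor of 50, 3 genes remained, Uty dropped out, and Kdm5d read 55.3 on the wild-type array, close to that floor. The mean over probe sets gave -0.14 for the outer root sheath and 0.22 for the unfolded protein response, and a floor of 50 gave -0.19 for Schwann cells and nerve. Except where a shift of all ratios or fewer dim genes accounts for a value, the cause was not tested.

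The epidermis, melanocyte, outer root sheath and sterol synthesis lists stayed outside the central 95% on the same side in 12 of 12 alternatives, Schwann cells and nerve and the sex-linked list in 11, the unfolded protein response and oxidative phosphorylation in 10, and the immune list in 8 of 11. Some of these alternatives could hardly have moved a percentile. No rescaling nearly equals the main setting, and equal medians and equal spiked controls shift a list and its random lists by nearly the same amount. Unmatched random lists leave the list medians themselves unchanged. The unfolded protein response fell inside with unmatched random lists and without probe sets that can match several transcripts, and the immune list without these probe sets, with the 60th percentile floor and with the pseudocount. Of the 25 lists within the central 95%, 8 lay outside it under at least 1 alternative. These were the adipocyte and endothelial lists with higher floors, the endothelial list also with the lower one, the follicle transcription factors with the mean over probe sets, the hair shaft keratins with the latter and with higher floors, sebaceous markers without probe sets that can match several transcripts, skeletal muscle with unmatched random lists, the FGF and mitogen-activated protein kinase targets with a floor of 50 (-0.19, percentile 2.45), and the insulin-like growth factor axis in 4 settings at percentiles up to 97.65. Of 405 list medians under the alternatives, 39 changed sign, among them that of the FGF and mitogen-activated protein kinase targets, at 0.050 with equal spiked controls. Of 1732 values of 159 named genes under the alternatives, 1499 moved by less than the spread between probe sets, 232 moved by more, and 1, of a gene that was 2-fold apart, changed sign. Counting values of any size, 9 changed sign. The gene 2-fold apart was Exosc1, which went to -0.49 without probe sets that can match several transcripts, since its brightest probe set is then left out.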

Other observations

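The test on retinoid genes and the gene cluster were chosen only after the result was seen, as were the genes named here.

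Several genes that supply or respond to retinoic acid read lower on the transgenic array beside Aldh1a3. Of 23 genes of retinoid metabolism and signalling on the arrays, 17 were above the floor on both and 5 of these (29.4%) were 2-fold lower, with 0 higher. Among all 11565 genes above the floor on both arrays, 183 were 2-fold lower. Because the list was chosen after the values were seen, this contrast is no test. The 5 lower genes were Aldh1a3, the retinoic acid receptor gene Rarb (48.4 and 19.1), the alcohol dehydrogenase gene Adh1 (188 and 75.9), the retinoic acid binding protein gene Crabp2 (571 and 265) and the retinol transporter gene Stra6 (345 and 163). Aldh1a2, a relative of Aldh1a3, read 18.4 and 36.7, and Cyp26b1, which degrades retinoic acid, 38.5 and 63.7. As a whole the list was not lower than matched random lists, with a median log2 ratio of -0.03 at percentile 30.4. Of 19 members above the floor on at least 1 array, 8 had ratios above 1. Whether a part of the list is lower stays open, since a median over members that go both ways does not decide that.

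Subfamilies of keratin-associated proteins, which are bright on both arrays, went different ways. All 6 measured members of subfamily 19 were lower on the transgenic array, with log2 ratios from -1.68 for Krtap19-1 to -0.11 for Krtap19-9b, the one that turned higher with equal spiked controls. All 3 members of subfamily 6 were higher, from 0.02 for Krtap6-5, which turned lower with equal medians, to 1.68 for Krtap6-3. All 4 members of subfamily 5 had ratios above 1, from 0.01 for Krtap5-5 to 1.09 for Krtap5-2 on the log2 scale, and 3 of them turned lower with equal medians. The 5 members of subfamily 4 lay between -0.06 and 0.04. Signal shared within a subfamily makes these values uncertain, and the probe set that reads Krtap19-1 at 3738 and 1170 is set against another that went up from 81.8 to 106. No explanation of these values was tested.

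Of the 183 genes that were 2-fold lower, 9 are neighbours in the epidermal differentiation complex, here the genes from S100a10 to S100a1 in assembly GRCm38.p6. Of 29 genes of the complex above the floor on both arrays, these 9 (31.0%) were 2-fold lower, against 1.51% of 11536 genes outside it, and 1, Lce1c, was 2-fold higher. The 9 were Lce3c, Sprr1b, Sprr2h, S100a9, Ivl, S100a8, Tchhl1, Sprr2f and Rptn. Of 15 members with a signal over 1000 on either array, 5 were 2-fold lower and 10 under 2-fold apart. Of these 10, 7 had log2 ratios near 0, namely S100a3 (0.09), Sprr1a (0.04), Prr9 (0.02), Tchh (0.01), S100a14 (-0.09), Crct1 (-0.11) and S100a16 (-0.13), and 3 read lower, namely S100a10 (-0.87), S100a1 (-0.58) and S100a6 (-0.41). The 7 include the brightest member, Prr9 (12295 and 12502), and compression of ratios at such signals was not tested. Over the 38 genes of the complex above the floor on at least 1 array, the median was -0.40, below that of every one of 10000 matched random lists, with 11 ratios above 1. The complex was chosen because lower genes lie in it, and signal shared within the Lce and Sprr families makes their values uncertain. Lce3c, Sprr1b, Sprr2h, Ivl, S100a8 and S100a9 were part of the pattern for which epidermis and neutrophils were tested above. No explanation was tested for the complex as such.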
